A study of Mus musculus with 2 samples.

How the data were processed

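RNA was measured in 2 samples of mouse embryos at embryonic day 3.75, 1 library of whole blastocysts and 1 library of inner cell masses (ICMs) isolated by immunosurgery. Per the labels' protocols, RNA was extracted with a PicoPure kit, reverse transcribed and amplified with the NuGEN Ovation RNA-Seq system, and made into SOLiD fragment libraries. The embryos came from B6CBAF1 females crossed to CD-1 males, per the labels. How many embryos went into each library is not given in the sources used here. Amplified cDNA without molecular identifiers does not count independent molecules, so all intervals given here cover counting error only.

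The authors deposited 1 table with a whole-number read count and an RPKM value (reads per kilobase of gene length, scaled to a library total) per gene and library. The genome build was mm9, per the submitters' processing notes. The aligner, the gene annotation, the treatment of reads that map to several places and the use of strand are not given in the sources used here. RPKM divided by the read count kept 1 ratio between the libraries over all genes, so the authors used the same length for a gene in both deposited RPKM columns. That ratio put the ICM total behind RPKM at 0.842 of the whole-blastocyst total, whereas the deposited read counts of the listed genes summed to a ratio of 0.445. The totals behind RPKM therefore were not the sums of the listed reads. Which reads they held is not given in the sources used here. Because the treatment of reads that map to several places is not given, values of genes with near-identical copies in the genome are uncertain. Among the genes named here these include Gapdh (6 and 1 reads), Hspa8, Ldha, Actb, the ribosomal protein genes, the histone genes and the MHC class I genes.

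The table lists 19559 genes by symbol, each once. Of these, 19267 (98.5%) matched a current or older symbol in the RefSeq gene table of assembly GRCm38.p6, which served for names only. No coordinates are given because that assembly is not the build of the files. In 25 rows the symbol had turned into a calendar date and in 4 rows it was a number, and those rows were counted but not named. Older symbols were matched to the genes of the lists only where they are no other gene's current symbol.

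Differences were computed as log2((ICM RPKM + 1)/(whole-blastocyst RPKM + 1)), over the 8981 genes with an RPKM of 1 or more in at least 1 library. With the pseudocount of 1 this scale understates the change of low genes. Genes with a difference of 1 or more, or of -1 or less, were counted as at least 2-fold higher or lower. With 1 library per group there is no replicate and no test of the conditions, and no p-value was computed. A ratio of 2 RPKM values is given with an exact conditional (Clopper-Pearson) 95% interval from the read counts. Where a library had no read of a gene, the ratio was bounded by the exact 95% limit and with a floor of 3 reads in that library. The floor leaves out the counting error of the other library, so its bound can lie beyond the exact limit.

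Because the 2 libraries differed over most genes, differences are also given relative to the median over the 3013 genes with an RPKM of 5 or more in both libraries, which was -0.66. These are called centred values.

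Before the data were examined, 32 gene lists were fixed: epiblast and pluripotency, primitive endoderm, trophectoderm, tight junction and desmosome, apical domain and polarity, ion and water transport, signalling pathways (Hippo and Notch, FGF and ERK, Nodal and BMP, LIF and STAT3, Wnt), basement membrane and matrix, DNA methylation machinery, chromatin regulators, glycolysis, cholesterol synthesis, oxidative phosphorylation, immediate early genes, heat shock and unfolded protein, p53 targets and apoptosis, cell cycle, imprinted genes, ribosomal proteins, replication histones, housekeeping, mitochondrially encoded genes, oocyte and maternal genes, the 2-cell stage, and markers of other cells (blood and immune, cumulus and uterine, mesenchyme and fibroblasts, liver and neural). For each of the 25 lists with 5 or more measured genes, the median difference was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. This describes these 2 libraries, since genes are not replicates. Centring leaves these positions as they are. About 5% of lists (1.25 of the 25) would lie outside the central 95% by chance.

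The genes named were set by a rule fixed at the same time. It takes 20 lineage genes, the 12 highest and 12 lowest differences among genes with an RPKM of 5 or more in at least 1 library (unnamed gene models, microRNAs and small nucleolar RNAs passed over), up to 4 genes of each list with the largest difference, and the 5 highest RPKM values of each library. Some genes that the rule takes are not reported here. Other list members named in the text were chosen after their values were seen.

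The computations were tested on simulated Poisson counts drawn from the mean of the 2 libraries, with 200 genes of 50 or more expected whole-blastocyst reads changed. The simulated ICM depth was set from the ratio of the totals behind RPKM and the median shift. These counts hold no scatter from amplification, so they check the computations and not the error of these 2 libraries. Over 8563 simulated genes, 100% of the genes raised 4-fold (49 genes) or 8-fold (50 genes) were recovered after centring. Of those lowered to 0.25 of their level, 81.2% were recovered, and of those lowered to 0.125, 80.4%. Of 200 simulated lists of unchanged genes, 8 lay outside the central 95% of random lists. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The alternatives tried were other pseudocounts, filters on low values, scalings between the libraries, a 4-fold threshold, and lists without shared genes.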

Results

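The transcriptome of the mouse blastocyst at E3.75 was compared with that of its inner cell mass (ICM). At this stage the embryo is a hollow ball with an outer epithelium, the trophectoderm, which gives rise to the placenta, and the ICM, which holds the precursors of the epiblast (the future fetus) and of the primitive endoderm (the future yolk sac). In immunosurgery, antibody and complement lyse the outer cells and leave the ICM. The whole blastocyst contains its ICM, so the comparison asks which transcripts are concentrated in the ICM and which are lost with the outer layer. Loss of the outer layer alone can raise a gene's ratio only up to the inverse of the ICM's share of the blastocyst's RNA. That share was not measured, so high ratios below may also reflect other differences between the 2 libraries. There was 1 library of each kind. The whole-blastocyst library held 9271198 reads on listed genes and the ICM library 4125479. At least 1 read was found for 12795 genes in the whole blastocyst and for 11608 in the ICM. With the whole-blastocyst reads drawn down to the ICM depth, 12057 genes had a read there. There were no replicates, so no difference could be set against a spread between samples, and the intervals below are 95% counting intervals of these 2 libraries.

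Most transcripts had a lower RPKM in the ICM library. Of 8981 genes, 805 were at least 2-fold higher in the ICM, 3950 were at least 2-fold lower, and 4226 were within 2-fold. The median difference over all these genes was -0.84 on the log2 scale. Over genes with an RPKM of 5 or more in both libraries it was -0.66. Relative to that shift, 1516 genes were at least 2-fold higher and 1838 at least 2-fold lower, so the higher genes made up 45.2% of those past 2-fold, compared with 16.9% as deposited. The ratios and shares below are as deposited unless said otherwise, and centring multiplies each ratio of ICM to whole blastocyst by 1.58. The listed genes took a smaller part of the total behind RPKM in the ICM library, at 0.528 of the whole-blastocyst value. Across genes, which are not independent replicates, the Spearman correlation of the libraries was 0.67. Of the genes past 2-fold, 118 of the higher and 357 of the lower ones had under 50 reads in both libraries.

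**Figure D1:**
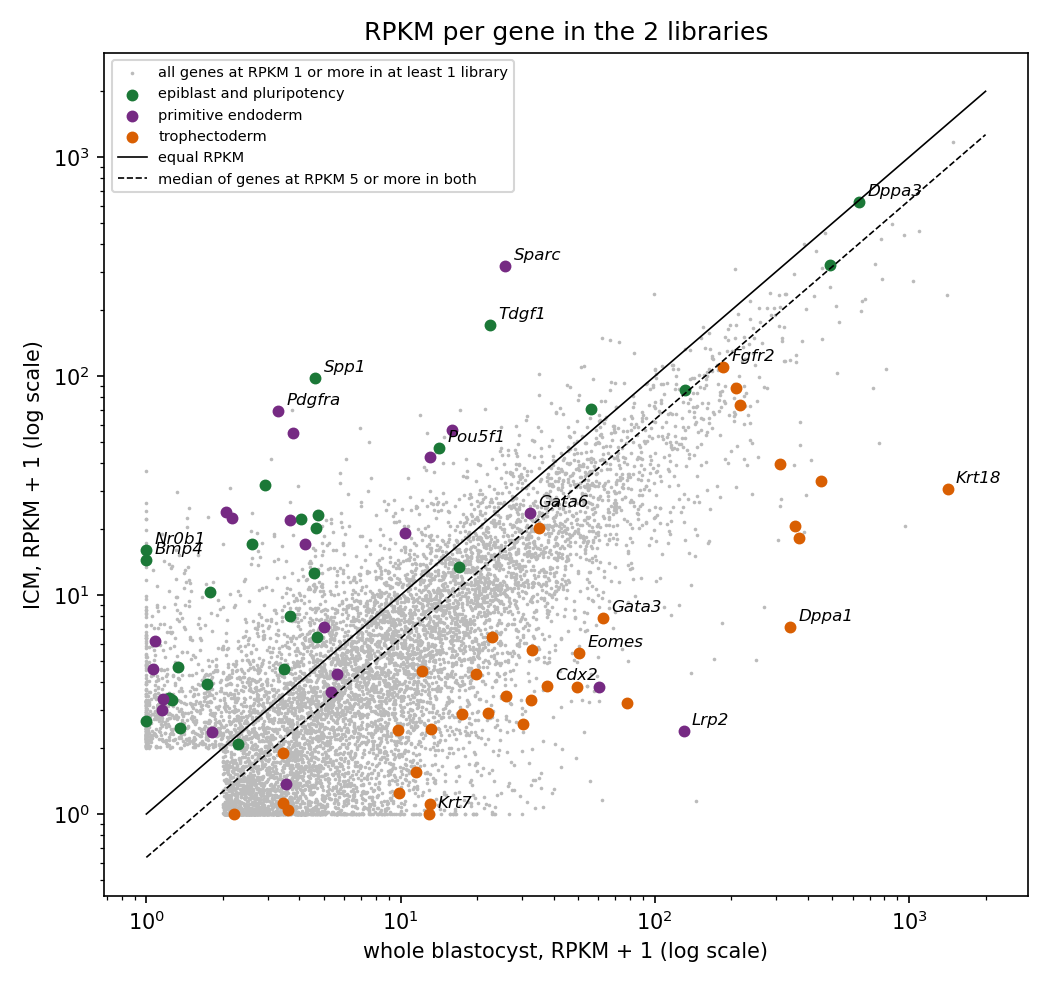
RPKM + 1 of each gene in the whole blastocyst (x axis, log scale) and the ICM (y axis, log scale), for the 8981 genes with an RPKM of 1 or more in at least 1 library, with 3 lineage lists in colour. Trophectoderm genes lie below the dashed line, which marks the median shift of -0.66, and all 27 epiblast and pluripotency genes lie above it.

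Epiblast and pluripotency genes were higher in the ICM library. Of 27 measured genes, 18 were at least 2-fold higher, none was 2-fold lower and 9 were within 2-fold. Relative to the shift, 22 were at least 2-fold higher and all 27 were above the centre. Pou5f1, the transcription factor OCT4, had an RPKM of 13.2 in the whole blastocyst and 46.0 in the ICM, a ratio of 3.49 (3.05 to 4.003). Nanog rested on 21 and 71 reads and was 4.01-fold higher (2.44 to 6.88). Tdgf1, the Nodal co-receptor Cripto, went from 21.5 to 170.4 (7.93-fold, 7.46 to 8.44). Esrrb was 12.02-fold higher (9.76 to 14.9), Fgf4, the ligand that directs neighbouring cells to primitive endoderm, 8.96-fold (6.07 to 13.7) and Klf2 2.64-fold (2.09 to 3.34). Sox2 had a ratio of 1.46 (1.24 to 1.72), which is 2.30 relative to the shift. The largest differences of the list were those of the secreted phosphoprotein gene Spp1 (3.63 to 97.2) and of Utf1 (1.94 to 30.8), and of Nr0b1 and Bmp4, which had no read in the whole blastocyst and 337 and 608 reads in the ICM. Against a floor of 3 reads, Nr0b1 was at least 133-fold and Bmp4 at least 241-fold higher. Some genes of the list were abundant in both libraries. Dppa3 had an RPKM of 633.8 in the whole blastocyst and 620.4 in the ICM (ratio 0.979, 0.951 to 1.01), Fbxo15 had 486.9 and 319.5, and Tcfcp2l1 (current symbol Tfcp2l1) 130.3 and 85.3. The median difference of the list was 1.46, or 1.47 with the genes without a whole-blastocyst read at their bound, above that of all 10000 random lists.

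**Figure D2:**
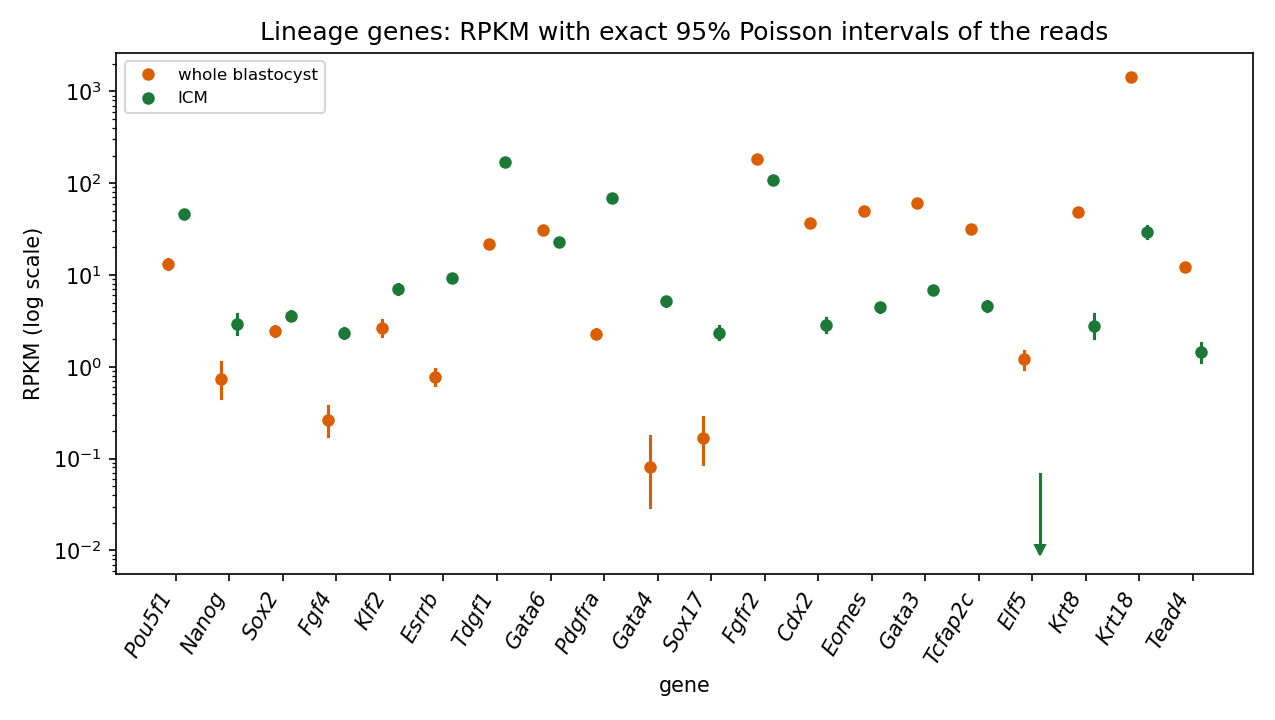
RPKM (log scale) of the 20 lineage genes in the whole blastocyst and the ICM (points), with exact 95% Poisson intervals of the reads (vertical lines) and a downward arrow from the upper limit for Elf5, which had no ICM read. Pdgfra stands at 2.29 and 68.1, and Krt18 at 1418 and 29.4.

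Most primitive endoderm genes were also higher in the ICM. Of 22 measured genes, 13 were at least 2-fold higher and 3 at least 2-fold lower (16 and 2 relative to the shift), and the median of 1.62 lay above all 10000 random lists. The 14 genes that stand in no other list had a lower median, 0.70, also above all 10000 random lists. Pdgfra, the receptor that marks this lineage, went from 2.29 to 68.1 (29.8-fold, 26.7 to 33.3). The transcription factors Gata4 (6 and 320 reads) and Sox17 (13 and 155 reads) were 63.3-fold (28.8 to 174) and 14.2-fold (8.04 to 27.2) higher. Gata6 was not, at 31.2 and 22.7 (ratio 0.727, 0.674 to 0.783), which relative to the shift was a difference of 0.21. Serpinh1, a chaperone of collagen folding, was 19.5-fold higher (16.3 to 23.4). The 3 genes on the other side were Lrp2, the endocytic receptor megalin (128.7 to 1.38, 93.1-fold lower, 74.4 to 118), its adaptor Dab2 (59.6 to 2.79, 21.3-fold lower, 18.5 to 24.7) and Runx1 (2.53 to 0.374).

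Of the 16 measured genes of basement membrane and matrix, 10 were at least 2-fold higher in the ICM and 4 lower (10 and 2 relative to the shift). Sparc, a matrix glycoprotein, reached an RPKM of 316.4 in the ICM from 24.8 in the whole blastocyst (12.8-fold, 12.04 to 13.5). The collagen IV gene Col4a1 was 21.8-fold (17.1 to 28.2) and the laminin gene Lama1 7.87-fold (5.69 to 11.1) higher. Nid2 had 362 reads in the whole blastocyst and none in the ICM. By the exact 95% limit it was at least 82.3-fold lower (102-fold at a floor of 3 reads), while Nid1 was 2.22-fold higher. The median of 1.20 lay above all 10000 random lists. Part of these genes also stand in other lists. The 10 genes that stand in no other list had a median of -0.41, above 88.3% of random lists and so inside their central 95%.

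Trophectoderm genes were low in the ICM library. Of 34 measured genes, 31 were at least 2-fold lower (26 relative to the shift) and none was 2-fold higher. The median of -2.91 (-2.95 with genes without an ICM read at their bound) lay below all 10000 random lists. The keratin gene Krt18 had the second highest RPKM of the whole blastocyst, 1418, and 29.4 in the ICM (48.2-fold lower, 41.9 to 55.6). Its partner Krt8 was 17.2-fold lower (12.7 to 23.7). Of the lineage transcription factors, Cdx2 was lower 12.9-fold (10.8 to 15.5), Eomes 11.1-fold (9.89 to 12.5), Gata3 8.98-fold (8.11 to 9.96), Tead4 8.46-fold (6.64 to 10.9) and Tcfap2c (current symbol Tfap2c) 6.97-fold (6.14 to 7.95). Elf5 had 77 reads in the whole blastocyst and none in the ICM, at least 21.6-fold lower. Dppa1 (339.8 to 6.12), Id2 (76.5 to 2.21) and the fatty acid binding protein gene Fabp3 (369.4 to 17.3) had the largest other differences of the list. Fgfr2, a receptor for FGF4, had 184.6 and 109.4 (1.69-fold lower, 1.64 to 1.74), a difference of -0.09 relative to the shift. All but 2 of the 34 genes had reads in the ICM library. Over the 31 genes of the list with 100 or more whole-blastocyst reads, the median ICM level was 9.01% of the whole-blastocyst RPKM, and it was 2.08% (1.80 to 2.39) for Krt18. Relative to the shift these shares were 14.2% and 3.28%.

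Genes of epithelial junctions were also low in the ICM library. Of 18 measured tight junction and desmosome genes, 15 were at least 2-fold lower and none higher (13 and 1 relative to the shift), with a median of -2.39 (-2.61 with zeros at their bound) below all 10000 random lists. The claudin genes Cldn6 and Cldn7 were 32.2-fold (22.8 to 47.0) and 20.1-fold (13.8 to 30.5) lower, and the desmosomal plaque gene Dsp 18.7-fold (16.4 to 21.5). Tjp1, which encodes ZO-1, had 67.8 and 58.1. Of 14 apical domain and polarity genes, 7 were at least 2-fold lower and none higher (2 each relative to the shift), and the median of -1.06 was inside the range of random lists. The cortical linkers Msn and Slc9a3r1 were 9.25-fold (8.91 to 9.61) and 11.996-fold (8.89 to 16.5) lower. Of 14 ion and water transport genes, 9 were at least 2-fold lower and 2 higher (3 and 2 relative to the shift), with a median of -1.30 inside the range of random lists. Among them the glucose transporter gene Slc2a3 went from 761.7 to 48.7, and the aquaporin genes Aqp3 from 310.8 to 38.6 and Aqp9 from 39.4 to 1.09. The carbonic anhydrase gene Car2 was 50.6-fold higher in the ICM (31.4 to 87.3).

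**Figure D3:**
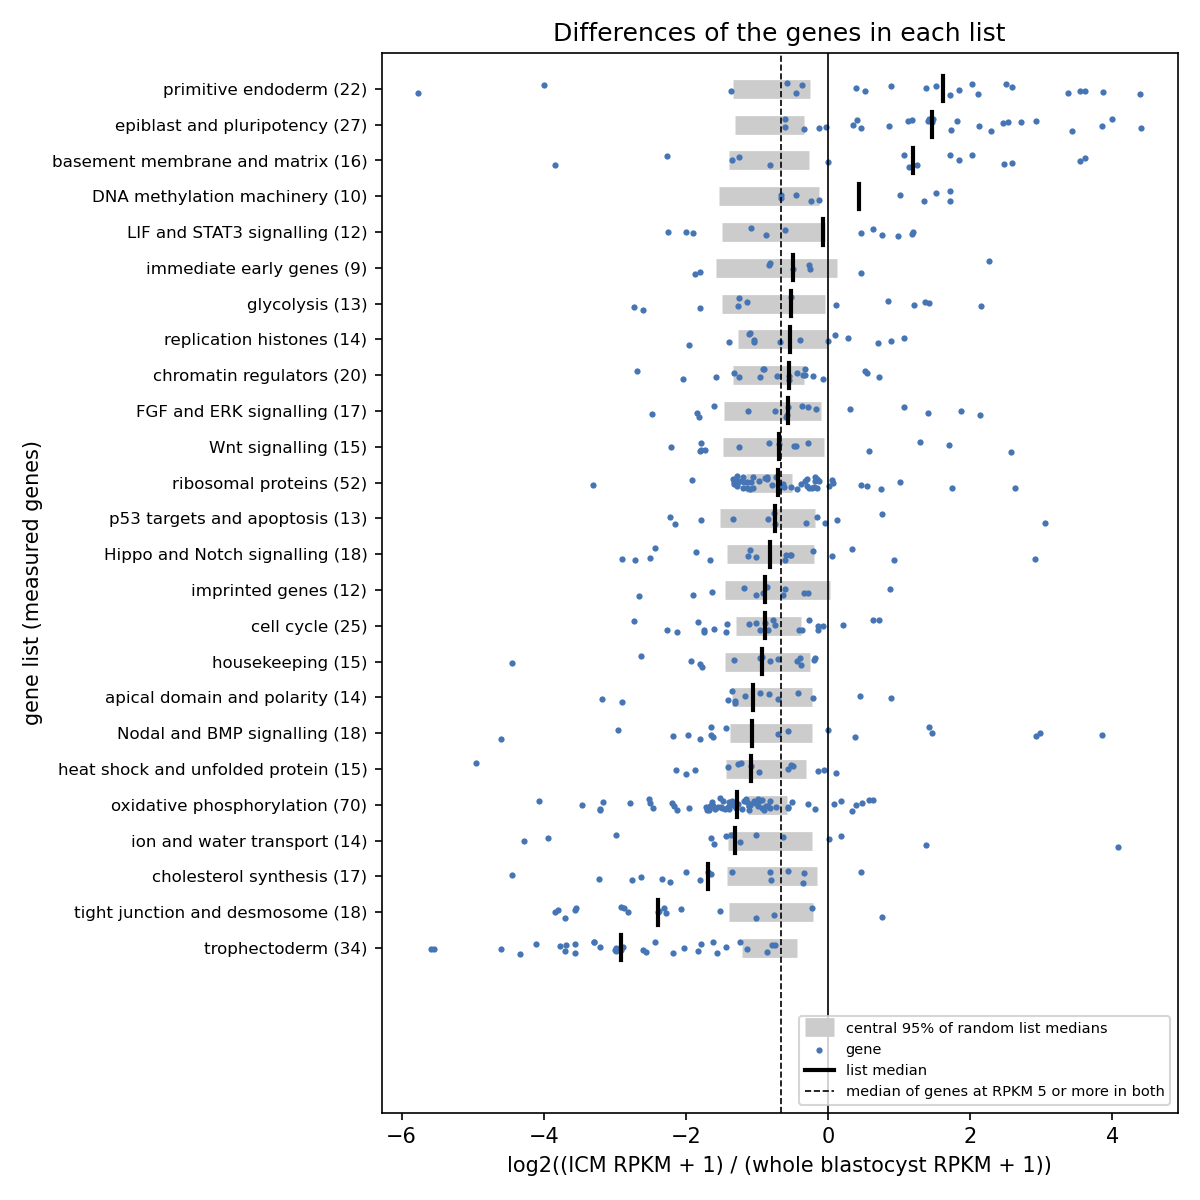
Log2 difference of each measured gene (points) of the 25 lists with 5 or more measured genes, with the list median (black bar) and the central 95% of the medians of 10000 matched random lists (grey). The dashed line marks the median shift of -0.66. The primitive endoderm and epiblast lists lie farthest to the right and the trophectoderm list farthest to the left.

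The signalling lists held genes on both sides, and none of their medians left the central 95% of random lists as measured. The Nodal and BMP list did so in opposite directions under other settings, at percentile 2.14 without genes of other lists and at 98.35 without a filter on low values. In the FGF and ERK list, 4 of 17 genes were at least 2-fold higher and 5 lower (4 and 3 relative to the shift). The ERK feedback gene Spry4 (11 and 621 reads) was 67.0-fold higher (37.2 to 135) and the ERK target Etv5 4.82-fold (4.18 to 5.57), whereas the phosphatase gene Dusp4 was 7.72-fold lower (6.39 to 9.41). In the Nodal and BMP list, 5 of 18 genes were higher and 9 lower (6 and 5 relative to the shift), with Bmp4 and Id3 (0.477 to 10.7) among the former and Id2 and Acvr2b (73 and 0 reads) among the latter. In the LIF and STAT3 list, 2 of 12 were higher and 4 lower (6 and 3 relative to the shift). Lif itself was 17.1-fold lower (11.9 to 25.4) and the STAT3 target Socs3 (5 and 118 reads) 28.0-fold higher (11.7 to 87.9). In the Wnt list, 3 of 15 were higher and 6 lower (4 and 5 relative to the shift). Axin2, a target of the pathway, was 8.21-fold higher (6.91 to 9.82), and the ligand genes Wnt3a (337 and 0 reads) and Wnt7b (285 and 4 reads) were lower. In the Hippo and Notch list, 1 of 18 was higher and 9 lower (2 and 6 relative to the shift). The higher one was Ctgf at 28.6-fold (18.1 to 47.9), and Tead2 was 14.3-fold lower (9.81 to 21.5).

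Genes of the DNA methylation machinery were higher in the ICM library. Of 10 measured genes, 5 were at least 2-fold higher and none 2-fold lower, also relative to the shift, and the median of 0.44 lay above 9995 of 10000 random lists. The de novo methyltransferase gene Dnmt3a was 3.72-fold (3.43 to 4.05), its cofactor Dnmt3l 3.45-fold (2.98 to 4.004), Uhrf2 3.28-fold (2.79 to 3.86) and Uhrf1, which recruits the maintenance enzyme, 3.15-fold (2.57 to 3.87) higher. Dnmt1 was not, at 14.1 and 8.54. The chromatin regulators had a median of -0.55 within the random range, with 5 of 20 genes at least 2-fold lower, Ehmt2 at 5.02-fold (3.76 to 6.83) among them, and none higher (2 and 3 relative to the shift).

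Genes of 2 metabolic pathways were lower in the ICM than random lists. Of 17 cholesterol synthesis genes, 11 were at least 2-fold lower and none higher (9 and 1 relative to the shift), and the median of -1.68 lay above only 33 of 10000 random lists. Sqle, squalene epoxidase (567 and 5 reads), was 95.5-fold lower (40.7 to 295), Cyp51 10.8-fold (9.08 to 12.9) and Insig1 6.92-fold (6.30 to 7.62). Of 70 nuclear genes of oxidative phosphorylation, 47 were at least 2-fold lower and none higher (16 and 4 relative to the shift), and the median of -1.28 lay above only 6 of 10000 random lists. The largest differences were in complex I genes, such as Ndufa5 (162.3 to 16.7) and Ndufv1 (32.6 to 2.64). Of 13 glycolysis genes, 4 were higher and 6 lower (5 and 3 relative to the shift), with a median of -0.52 within the random range. The hexokinase gene Hk2 was 6.88-fold lower (6.58 to 7.19) and Ldha, a lactate dehydrogenase gene, 6.05-fold higher (4.61 to 8.03).

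The remaining lists lay within the random range. The cell cycle list had 11 of 25 genes at least 2-fold lower and none higher (6 and 2 relative to the shift), with Plk1 (210 and 11 reads) and Ccnb1 (402 and 39 reads) farthest. The p53 and apoptosis list had 4 of 13 lower and 1 higher (3 and 2 relative to the shift). The higher one was Pmaip1, which encodes NOXA, at 9.55-fold (8.78 to 10.4). Among 9 immediate early genes, which stress can induce, 1 was higher, Egr1 with 3 and 373 reads, and 2 were lower (2 each relative to the shift). Of 15 heat shock and unfolded protein genes, 8 were lower and none higher (4 and none relative to the shift). The imprinted list had 5 of 12 genes lower and none higher (2 and 1 relative to the shift), Xist (14.2 to 1.41) and Peg3 (4.21 to 0.393) among them. Of 15 housekeeping genes, 6 were lower and none higher (5 and none relative to the shift), including Actb (1035 to 272.4) and B2m (42.0 to 0.979). The ribosomal protein list had 20 of 52 genes lower and 3 higher, with a median of -0.71, and the replication histones 6 of 14 lower and 1 higher. Relative to the shift, 2 ribosomal protein genes were lower and 6 higher, as were 1 and 3 replication histone genes.

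Markers of other cells were few. In the blood and immune list 4 of 17 genes reached an RPKM of 1, all with at most 66 reads in either library. In the cumulus and uterine list 4 of 18 did, with Cyp11a1 at 324 and 0 reads, Wfdc2 at 158 and 7, Cyp19a1 at 0 and 91 and Star at 239 and 61. In the mesenchyme list 2 of 14 did, Vim (7 and 289 reads) and Thy1 (6 and 351). No gene of the liver and neural list did. Of 20 oocyte and maternal genes 3 did, including 2410004A20Rik (current symbol Khdc3) with an RPKM of 59.95 and 53.04, and of 9 genes of the 2-cell stage list 1 did, Eif1a. Mitochondrially encoded genes were not analysed here.

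The 12 highest named differences were those of Ghrhr, Butr1, Wdr54, Ckap4, Spp1, Pdgfra, Cpe, Flrt3, Car2, Nr0b1, Vim and Serpinh1. Of these, Ghrhr (491 ICM reads), Butr1 (186), Wdr54 (163), Cpe (479), Flrt3 (2189) and Nr0b1 (337) had no read in the whole blastocyst. In all, 125 genes had 50 or more reads in the ICM and none in the whole blastocyst. Chemosensory receptor genes made up 12 of them (9.60%). They were 17.5% of the 6764 genes without a whole-blastocyst read and 0.44% of the 6373 genes with 50 or more ICM reads. Ckap4, a membrane protein of the endoplasmic reticulum, was 88.2-fold higher (63.5 to 126). The 12 lowest were Lrp2, Serpinb6c, Klk7, Dppa1, Krt18, Adh1, Slco4c1, Slc6a14, Lgals1, Slc28a3, Lmo7 and Hspa8. Klk7, a serine protease gene, went from 248.4 to 4.07, the alcohol dehydrogenase gene Adh1 from 964.7 to 19.8, the galectin gene Lgals1 from 170.0 to 4.12 and the nucleoside transporter gene Slc28a3 from 138.4 to 3.40. Serpinb6c, Slc6a14 and Hspa8 rested on 3 ICM reads each and Lmo7 on 2. Hspa8 has near-identical copies in the genome, so its reads are uncertain. By RPKM, Ywhae led both libraries (1484 and 1167), followed in the whole blastocyst by Krt18, Cd63 (1408), Malat1 (1092) and Actb, and in the ICM by Dppa3, Rab7 (493.3), Malat1 (460.8) and Arf3 (448.0). The rank of a gene within a library depends on the length used for RPKM, which is not given in the sources used here.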

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

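The size of the excess of lower genes depended on the scaling between the libraries. As deposited, 805 genes were higher and 3950 lower. Centring gave 1516 and 1838, TPM 1767 and 2264, quantile normalization 1682 and 1893, and scaling to the listed gene reads, chosen after seeing the data, 1718 and 2312. Lower genes outnumbered higher ones under each of these scalings, and the higher share went from 16.9% as deposited to between 42.6% and 47.0%. The median over genes with an RPKM of 5 or more in both libraries changed sign. It went from -0.66 to 0.18 with quantile normalization, 0.21 with listed gene reads and 0.25 with TPM. Over all tested genes the median stayed negative, at -0.08, -0.13 and -0.09. The medians of the FGF and ERK, LIF and STAT3, chromatin regulator, glycolysis and immediate early lists were negative as deposited and positive after centring and after quantile normalization. That of replication histones was positive only after centring, and those of the Wnt, p53 and ribosomal protein lists (0.10 each) only after quantile normalization. Counts also depended on the treatment of low values and on the threshold. A pseudocount of 5 gave 221 higher and 1761 lower, a filter at an RPKM of 5 gave 362 and 2590, with 5323 genes tested, and a 4-fold threshold gave 198 and 1202. A pseudocount of 0.1 (1032 and 4599) and a filter at 50 reads (687 and 3593, chosen after seeing the data) stayed within 1.5 times. Leaving out the filter or summing rows of a symbol could not change the counts, since no gene under an RPKM of 1 can pass 2-fold at this pseudocount and no symbol repeats. The lists kept their side of the central 95% under every alternative run, with 3 exceptions. Without genes that stand in more than 1 list, basement membrane and matrix moved to percentile 88.3 and Nodal and BMP signalling to 2.14, and without a filter Nodal and BMP signalling moved to 98.35, where its median was 0 because unmeasured genes entered. The median of the primitive endoderm list, 1.62, was 0.70 without shared genes and without a filter, 2.02 at an RPKM filter of 5, and 2.09 and 0.72 at pseudocounts of 0.1 and 5. At these pseudocounts those of the epiblast list were 2.36 and 0.65 and those of the trophectoderm list -3.49 and -1.75, and at the RPKM filter of 5 they were 2.12 and -2.98. Replication histones gave no value at an RPKM filter of 5, with under 5 genes left. Between 79 and 112 of the named genes moved by more than their counting error under a given pseudocount or scaling. Those counted as unmoved, between 48 and 81, include every named gene without a read in 1 library, since its counting error has no bound. No named gene past 2-fold changed its direction, but only quantile normalization could have reversed one. A pseudocount cannot change the sign of a difference, and centring and TPM shift it by less than 1 on the log2 scale. No replicate could be left out and no paired analysis was possible because each group has 1 library. Depth limits low genes most: Nanog rests on 21 and 71 reads, and a gene with 0 ICM reads is bounded only at 3 reads.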

Other observations

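The tests of genes without whole-blastocyst reads and of trophectoderm transcripts in the ICM, and the 4 gene lists described next, were chosen after the values had been seen; the tests of GC content and transcript length were set before their results.

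These 4 lists hold genes already seen to differ, such as Ckap4, Serpinh1 and Lmo7, so their values describe the members and test nothing. Of 20 measured genes of collagen processing and the secretory pathway, 7 were at least 2-fold higher in the ICM, 2 lower and 11 within 2-fold (9 higher and 1 lower relative to the shift). The median of -0.06 and the mean of 0.88 differ in sign as deposited, and relative to the shift the median was 0.60. Besides Ckap4 and Serpinh1, the prolyl hydroxylase gene P4ha1 was 34.9-fold (24.6 to 51.3) and the retrieval receptor gene Kdelr3 10.6-fold (7.92 to 14.4) higher. Of 20 genes of the nuclear lamina and of actin cross-linking, 17 were at least 2-fold lower (12 relative to the shift), with a median of -2.19. Lmna, which encodes lamins A and C, was 59.9-fold lower (41.6 to 89.6) and Csrp1 28.4-fold (25.3 to 32.0). Of 7 measured genes of MHC class I presentation, 5 were at least 2-fold lower and none higher (4 and 2 relative to the shift), with H2-K1 at 64.7-fold (36.8 to 126) and B2m at 42.9-fold (26.2 to 75.3), and a median of -1.69. Of 27 lysosome genes, 13 were at least 2-fold lower and 1 higher (10 and 2 relative to the shift), with a median of -0.97, and Gm2a, Psap and Cd63 were 18.02-fold, 8.18-fold and 6.01-fold lower.

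A whole blastocyst contains its ICM, yet 125 genes had 50 or more ICM reads and no whole-blastocyst read, led by Flrt3 with 2189, and 25 of them had 200 or more. Removal of the trophectoderm alone would keep each gene's whole-blastocyst level at or above its ICM level times the ICM's share of the blastocyst's RNA. That share was not measured, so whether removal alone could leave such zeros stays open. Over all 6373 genes with 50 or more ICM reads, Poisson counting gives 2.46 zeros at the share of Esrrb (8.32%). At that of Pdgfra (3.36%) it gives 95.6. Over all genes with 200 or more it gives 0.0832 at that of Pdgfra and 40.3 at that of Ckap4 (1.13%). These counts treat amplified reads as independent and give every gene the same share. Pdgfra and Ckap4 are among the 12 highest differences of these same libraries, so their shares cannot set the number expected from removal alone. At the floor of 3 reads, Flrt3 kept at most 0.115% of its ICM level, and removal alone would need an ICM share no higher than this. Random amplification of rare molecules in the ICM library stays open too. Chemosensory receptor genes made up 9.60% of the 125 genes (exact binomial interval 5.06 to 16.2). That was below their 17.5% of all genes without a whole-blastocyst read but not below the bound of 0.5 times that share. It was above their 0.44% (28 genes) of the 6373 genes with 50 or more ICM reads. Of the 7977 genes with 50 or more whole-blastocyst reads, 9 were receptor genes, 1 of them among the 329 without an ICM read. A difference in the stage or number of embryos, or a response to immunosurgery, was not tested.

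Trophectoderm transcripts in the ICM library may come from outer cells that survived lysis, which as the only source would give all genes of the list about the same ratio, apart from the scatter between 2 separately amplified libraries. Over the 31 genes with 100 or more whole-blastocyst reads the ICM level had a median of 9.01% of the whole-blastocyst RPKM (14.2% relative to the shift) and reached 59.2% for Fgfr2, while Krt7 had 150 whole-blastocyst reads and 0 ICM reads. The interquartile range of their log2 differences, 1.53, stood at percentile 86.07 among 10000 random sets matched on whole-blastocyst RPKM (median 1.20), and so not below their central 95%, as a single source was predicted to give, nor above it. The random genes may themselves differ between ICM and trophectoderm, so their range is not technical scatter alone, and whether a single source allows this range stays open. Low expression of trophectoderm genes in ICM cells is a biological explanation that was not tested.

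The lower level of oxidative phosphorylation genes in the ICM was checked against transcript properties, using the longest annotated transcript of each of the 70 genes and random lists matched on expression in 5 bins and on the property in 10 bins. These transcripts are short (median 1135 bases, against 3367 over all genes). Among lists matched on length the list's median of -1.28 stood at percentile 0.65. This argues against short transcripts as the whole cause, as far as 10 bins match the length. Within a bin the genes of the list may still be shorter than their matches. Matching on GC content (percentile 0.02) decides nothing, because the list's median GC content of 50.2% is close to the 49.0% of all genes and the matching could move little. Across genes, which are not independent replicates, the Spearman correlation of the difference was -0.01 with GC content and 0.04 with transcript length. A higher expression of these genes in the trophectoderm than in the ICM is a hypothesis that remains open, since 1 library per group cannot separate it from other differences between the preparations.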
